A study of Sus scrofa with 3 samples.

How the data were processed

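RNA was measured in 3 cultures of mesenchymal stem cells (MSC, also called mesenchymal stromal cells) grown from the adipose tissue of adult pigs. Per the labels' protocols, the cells were kept in advanced MEM, a cell culture medium, with human platelet lysate. Total RNA was taken with the miRNeasy kit, and 0.5 µg of it went into a TruSeq V2 RNA-Seq library, per the labels' protocols. The labels put all 3 samples in a single group, so no conditions could be compared. What could be measured was the level of each gene and its spread between the cultures. The cultures are called 1, 2 and 3 after the numbers in their labels. The labels do not say which animal each culture came from, so the spread between these samples may in part be technical. The p-values of the gene tests rest on that spread together with the spread of other genes of like level.

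The deposited values are RPKM (reads per kilobase of gene model, scaled to the reads of the library) for 30477 Ensembl genes, as the column names in the file header state. The genome build was susScr11, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Coordinates below are those of the deposited table, on susScr11. Multiplying each RPKM by the gene model's listed length plus 1 base, in kilobases, gave whole multiples of a single step in each column, within a tolerance of 1e-06 of a read, for 100% of the values. The authors therefore counted whole reads, and the columns sum to 51788677, 62248183 and 64774044 reads over the genes of the table. The deposited RPKM were scaled by these sums, with no adjustment for what kinds of RNA made up each library. At these depths 1 RPKM over a gene model of 2 kb corresponds to 104, 124 and 130 reads in cultures 1, 2 and 3. A count of 0 over such a gene allows up to 3 reads, which is 0.029, 0.024 and 0.023 RPKM, and this floor covers counting error only. All 37 genes of the mitochondrial chromosome are listed at 0 in each library, so a 0 there was not read as a measured absence.

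Gene names were those of the deposited table. For 14012 genes without a name there, 785 were named through a table that pairs Ensembl IDs with symbols. Without a stated strand, reads of overlapping genes cannot be told apart, and the named genes are pointed out where the reads of an overlapping gene are not few beside their own.

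The tests had been planned for read counts with a count model. The deposited unit is RPKM, so the tests were done with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), which understates differences of genes near or below the pseudocount of 0.5 RPKM. Planned CPM levels became RPKM levels, and the planned count filter became a mean of at least 1 RPKM. For each of 29479 genes with at least 1 read, limma's moderated test (trended prior variance, robust) asked whether the mean over the cultures lay above or below 1 RPKM. For 10474 genes with a mean of at least 1 RPKM, the variance between cultures was divided by limma's trended prior variance and tested by an F test with 2 residual degrees of freedom, upper tail, to find genes more variable than others of like level. Adjusted p-values are Benjamini-Hochberg values, and the threshold was 0.05. Both tests were tested on simulated data before use. In the simulation of the spread test on 10474 genes, 56% of 100 genes given a log2 SD of 2 were recovered and 81% of 100 given a log2 SD of 4, with 2 calls among 10274 unchanged genes. The unchanged genes were given spreads more alike than the data later showed, so these shares may overstate recovery in the data. In the simulation of the test against 1 RPKM on 29479 genes, 100% of the genes set at 4 RPKM and 100% of those set at 8 RPKM were called above, with 0 calls among 200 genes set at 1 RPKM.

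The 28 gene lists hold 409 entries, of which 356 were measured, and were fixed before the data were examined, as were the tests and most of the alternatives. For each list the median log2(RPKM + 0.5) was taken in each library and set against 10000 random lists of the same size. The spread of a list was the SD over the 3 cultures of its members' mean log2(RPKM + 0.5), set against 10000 random lists matched on level in 20 bins. This was done for the 18 lists that had at least 3 members with a mean of 1 RPKM or more. Percentiles describe these libraries, since genes are not replicates. Lists are reported with the counts of members above or below 1 RPKM over all genes tested, and with those adjusted over the list alone where the latter differ. The genes named are the 20 of highest mean CPM, the 3 members of highest mean CPM in each list, and each measured member of the MSC surface, MSC exclusion, pluripotency and sex-linked lists. A last part of the rule, the 25 genes of largest spread past the threshold, named none. Any other gene is said to have been chosen after its values were seen. A few genes that the rule names are not reported here, and they remain in the counts and list values.

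The alternatives tried were median-of-ratios size factors, other levels than 1 RPKM, other filters, a prior that is not robust, CPM in place of RPKM for the marker difference and the list levels, and leaving out each culture in turn. The size factors were taken over all genes with a read in each library, without a filter on level. Scaling to protein-coding reads, voom weights on the recovered reads, CPM for the gene counts and the spread, other pseudocounts for the 2 tests and the spread of the lists, and a restriction to protein-coding genes off chromosome Y were chosen after seeing the data. So were median-of-ratios factors for the marker difference and the list levels, a pseudocount of 1 RPKM for the list levels, a filter at a mean of 0.1 RPKM, and random lists from genes with a mean of at least 1 RPKM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the lists and figures. The libraries were compared before use, only to see whether one had been deposited more than once. Chi-square per degree of freedom over the recovered reads was 1306, 1626 and 472 for the pairs 1 and 2, 1 and 3, and 2 and 3, so no pair looked like the same library listed again. This test does not measure how well the cultures agree.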

Results

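RNA of 3 adipose-derived MSC cultures from adult pigs was sequenced to a depth of 51788677, 62248183 and 64774044 reads counted over genes in cultures 1, 2 and 3 (59603635 ± 6884778, SD, n = 3). The series belongs to work on MSC transplantation and the narrowing of the vein in arteriovenous fistulas, the vascular access used for hemodialysis. The labels name a single group, so the data address what these cells express and how far the cultures differ. Reads were seen over 28310, 28395 and 24503 genes, and 9875, 10749 and 10364 genes reached 1 RPKM. Protein-coding genes took 70.3%, 88.6% and 88.8% of the reads. Small non-coding RNA genes took 28.2%, 9.08% and 8.33%, most of it snoRNA, which are small nucleolar RNAs (23.2%, 7.87% and 7.06%). These shares count reads over overlapping entries more than once, and with 1 entry kept per small RNA locus the small RNA shares were 20.6%, 5.79% and 5.45%. The library of culture 1 thus stood apart from the others in composition, and this applies to each comparison between cultures below.

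**Figure D1:**
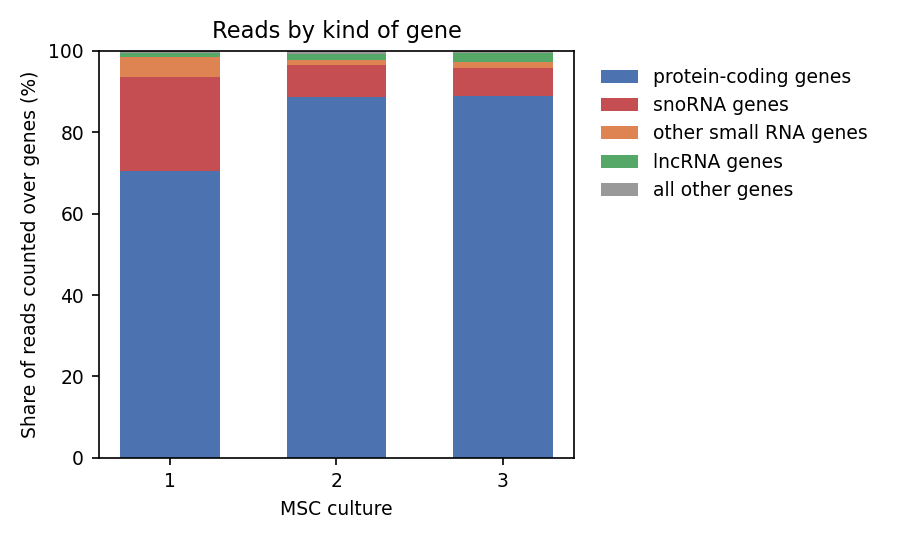
Share of the reads counted over genes (y axis, %) that fell on protein-coding, snoRNA, other small RNA, lncRNA and all other genes in each of the 3 MSC cultures (x axis), with 1 library per bar. Protein-coding genes took 70.3% in culture 1 and 88.6% and 88.8% in cultures 2 and 3.

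Genes of the extracellular matrix were among the most abundant. Fibronectin (FN1, ENSSSCG00000016174, chromosome 15, 117658099 to 117731014) ranked first by mean CPM, which does not divide by gene length, with 6910 ± 6115 RPKM (SD, n = 3). It took 1.28%, 4.81% and 11.5% of the reads in cultures 1, 2 and 3. The collagen genes COL3A1 (4353 ± 449 RPKM), COL1A2 (2861 ± 754), COL5A2 (758 ± 317), COL1A1 (608 ± 196) and COL12A1 (310 ± 58.4) were also among the 20 genes of highest mean CPM. The same 20 included thrombospondin 1 (THBS1, 1561 ± 675 RPKM) and SPARC (2014 ± 518), secreted proteins of the matrix. Vimentin (VIM, 1531 ± 367), the intermediate filament of mesenchymal cells, the gap junction protein GJA1 (1179 ± 334) and the translation factor EEF1A1 (5625 ± 384) were there too. COL5A2 shares part of its gene body with COL3A1, and without a known strand their reads cannot be fully told apart. The remaining 9 of the 20 entries were non-coding or tied to a non-coding RNA. These were a pair of U3 snoRNA loci on chromosome 12, each listed under overlapping entries, 1 of which took 7.64%, 2.66% and 2.70% of the reads (ENSSSCG00000040361). The others were the RNA of RNase P, RNase MRP, a U4 snRNA, an lncRNA without a name (ENSSSCG00000048856, chromosome 2, 6752140 to 6757157, 2181 ± 1381 RPKM) and ARHGEF39. The gene body of ARHGEF39 contains RNase MRP, and the reads of the 2 entries ran in parallel (0.69%, 0.20% and 0.14% of the total for both).

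The surface markers by which MSC are usually recognised were expressed in all 3 cultures, and most markers used to exclude blood cells were not. Of 7 measured surface markers, 6 lay above 1 RPKM in the limma test and 1, ALCAM, lay below. The integrin subunit ITGB1 (ENSSSCG00000011101, chromosome 10, 56078398 to 56173795) was highest at 203 ± 93.2 RPKM. The hyaluronan receptor CD44 followed at 78.4 ± 6.66, THY1 (CD90) at 65.9 ± 27.2, the ectonucleotidase NT5E (CD73) at 26.8 ± 11.6, the aminopeptidase ANPEP (CD13) at 16.3 ± 9.03 and endoglin (ENG, CD105) at 5.81 ± 2.47 (SD, n = 3 each). The largest of their 6 adjusted p-values in limma was 1.3e-08, for ENG, which was above 1 RPKM in 3 of 3 cultures. Such values lean on the spread of other genes and do not measure that of ENG alone, whose own log2 SD was 0.66. ALCAM (CD166) had 0.188 ± 0.086 RPKM (limma, adjusted p = 2.1e-08).

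Among 7 measured exclusion markers, 5 lay below 1 RPKM in the limma test. The leukocyte marker PTPRC (CD45) had 0.058 ± 0.043 RPKM, CD34 of hematopoietic and endothelial cells 0.085 ± 0.036 and the class II gene HLA-DRA 0.037 ± 0.035 (SD, n = 3 each). These values are of the size of the background, and the gene body of PTPRC also holds a pair of microRNA genes with reads. The median over 105 olfactory receptor genes, a family seldom expressed outside the olfactory epithelium, was 0.061, 0.051 and 0 RPKM in cultures 1, 2 and 3. ITGAM (CD11b) had 0.098, 0.143 and 1.21 RPKM. Its call below 1 RPKM (limma, adjusted p = 0.0099) was lost without culture 1 (adjusted p = 0.15) and without culture 2 (adjusted p = 0.10), with a pseudocount of 1 RPKM (adjusted p = 0.081) and with voom weights (adjusted p = 0.17). The 2 exclusion markers above 1 RPKM were CD14, a co-receptor for lipopolysaccharide, at 2.12 ± 0.289 RPKM, and CD79A at 89.1 ± 31.1 RPKM. The gene body of CD79A overlaps an unnamed protein-coding gene, ENSSSCG00000003042 (chromosome 6, 50000219 to 50009592), which had 261 ± 58.4 RPKM, so the reads listed for CD79A cannot be assigned to it. The median log2(RPKM + 0.5) of the surface markers exceeded that of the exclusion markers by 4.52, 5.86 and 5.92 in the 3 cultures, a mean of 5.43 ± 0.79 (SD, n = 3). Its size depends on the pseudocount, with 7.09 at 0.1 RPKM and 4.57 at 1 RPKM, since the exclusion markers lie near 0. The difference was positive in 3 of 3 cultures, and the exact two-sided sign-flip permutation test gave p = 0.25, the smallest that 3 libraries allow.

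**Figure D2:**
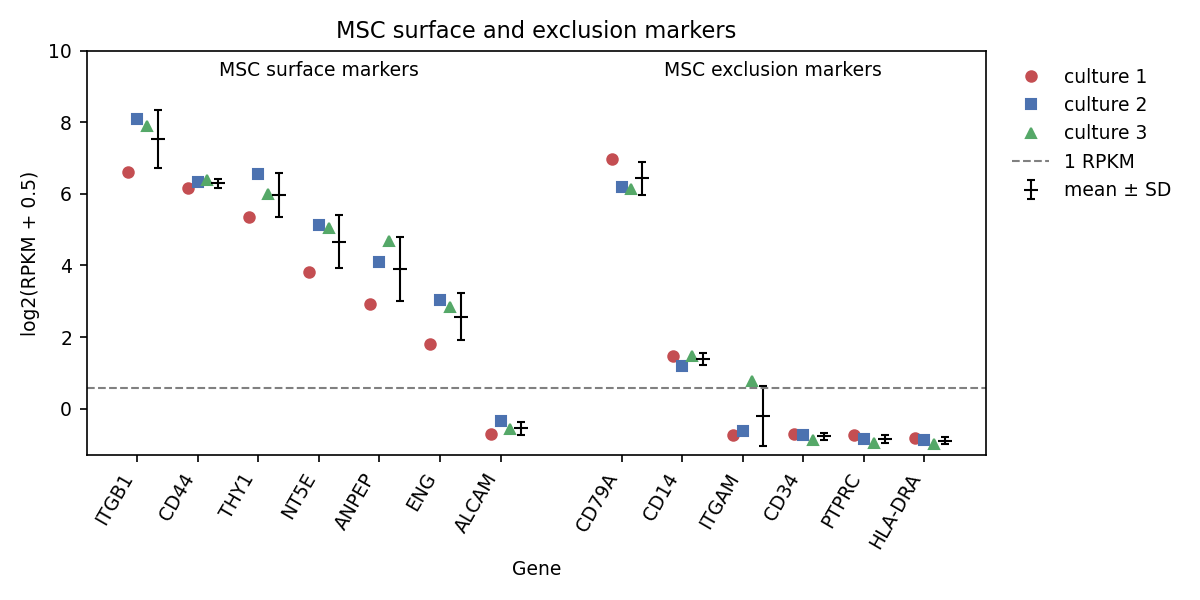
Expression of the 7 measured MSC surface markers and of 6 of the 7 measured exclusion markers (x axis) as log2(RPKM + 0.5) (y axis), with 1 point per culture, the mean ± SD of the 3 cultures in black and 1 RPKM as a dashed line. Of the surface markers 6 of 7 lie above the line, and of the exclusion markers CD79A, which overlaps another expressed gene, and CD14 do.

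Markers of adipose stromal progenitors were present in part. Of 12 measured members 7 lay above 1 RPKM and 3 below, and the list's median stood at percentile 99.5 of random lists from all genes with a read, but at 39.2 of those from genes with a mean of at least 1 RPKM. The growth factor receptors PDGFRA (161 ± 50.8 RPKM) and PDGFRB (25.2 ± 4.69) and the adhesion molecule VCAM1 (49.1 ± 13.8) were highest. Members below 1 RPKM were DLK1 (0.039 ± 0.034), LEPR (0.071 ± 0.058) and CD36 (0.043 ± 0.036), named after their values were seen.

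Markers of most other cell types that adipose tissue holds lay near background. Of 12 endothelial markers 10 were below 1 RPKM, among them VWF at 0.083 ± 0.032. The 2 above were ERG, a transcription factor, at 9.41 ± 6.83 RPKM, and PECAM1 at 1.92 ± 0.910. PECAM1 overlaps the abundant DDX5, and its call (limma, adjusted p = 0.024) was lost without culture 2 (adjusted p = 0.37) and without culture 3 (adjusted p = 0.053). Of 12 macrophage markers 9 were below and 2 above, namely LYZ (22.7 ± 1.59 RPKM) and FCER1G (7.31 ± 2.08), which each overlap another expressed gene, and TYROBP (1.15 ± 0.163) did not differ from 1 RPKM in the limma test. Of 11 lymphocyte markers 8 were below and 3 above, and those 3 (CD79A, CD3G at 33.3 ± 7.43 and CD247 at 3.02 ± 1.19) each overlap another expressed gene. Of 6 red cell and platelet markers 3 were below and 1 above, the integrin subunit ITGA2B (6.63 ± 1.48), while PPBP (0.830 ± 0.842) and GP9 (0.861 ± 0.249), which overlaps another gene with reads, were not decided. Of 9 epithelial and mesothelial markers 8 were below, among them CDH1 (0.171 ± 0.234, a call lost with voom weights at a limma adjusted p of 0.057) and EPCAM (0.197 ± 0.071), and KRT7 had 1.91 ± 1.40 RPKM and was not decided. Of 8 pericyte markers 4 were below and only PDGFRB above, with KCNJ8 at 0.993 ± 0.440, which overlaps another gene with reads, and CSPG4 at 3.23 ± 2.71 not decided.

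Genes of the differentiated lineages that MSC can form were low with a few exceptions. Of 10 adipocyte markers 8 were below 1 RPKM, GPD1 (0.665 ± 0.090) was not decided, and lipoprotein lipase (LPL) was above at 42.3 ± 11.2 RPKM. CEBPA, a transcription factor of adipocyte differentiation, had 0.598 ± 0.490, and its call below 1 RPKM (limma, adjusted p = 0.033) was lost without culture 2 (adjusted p = 0.23), without culture 3 (adjusted p = 0.39) and when scaled to protein-coding reads (adjusted p = 0.19). Of 10 osteogenic markers 5 were below and 3 above. The 3 were the transcription factor RUNX2 (9.92 ± 5.48), osteopontin (SPP1, with 8.18, 20.2 and 97.9 RPKM in cultures 1, 2 and 3) and DMP1 (6.16 ± 1.56), which overlaps DSPP. Of 9 chondrogenic markers 5 were below and 1 above, SOX9 at 2.17 ± 1.55, and that call was lost without culture 3 (limma, adjusted p = 0.022 with all cultures and 0.53 without it). COL11A1 (1.12 ± 0.698) and SOX6 (0.640 ± 0.303) were not decided. The 4 measured pluripotency genes, NANOG, LIN28A, LIN28B and TDGF1, were all below, at means of 0.027 to 0.10 RPKM and listed at 0 in culture 3, and TDGF1 overlaps another gene with reads. POU5F1, SOX2, SALL4 and UTF1 of that list were not matched by name, so their levels are not known here.

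Most genes of contraction, matrix and secretion on the lists were expressed. Members named here and in the next paragraph are among those of highest mean CPM in their list, which need not be those of highest RPKM. Of 14 smooth muscle contractile genes 10 were above 1 RPKM and 1 below, including ACTA2 (alpha smooth muscle actin, 356 ± 400 RPKM), CALD1 (249 ± 42.0) and TPM1 (80.9 ± 42.7). Of 21 extracellular matrix genes 19 were above and 0 below, and of 12 matrix turnover genes 10 were above and 0 below, with MMP2 at 449 ± 69.2 and the protease inhibitor TIMP3 at 268 ± 213 RPKM. Of 22 secreted growth factors 15 were above and 4 below, including CCN2 (230 ± 147), VEGFA (109 ± 65.4), which drives vessel growth, and KITLG (61.1 ± 34.4). Of 17 immune mediators 11 were above and 4 below, including the chemokine CCL2 (853 ± 110), LGALS1 (650 ± 267) and CXCL8 (372 ± 148). The medians of these 5 lists stood above percentile 99.9 of random lists from all genes with a read, most of which are below 1 RPKM. Against random lists from genes with a mean of at least 1 RPKM, the growth factors stood at percentile 53.2 and the other lists at 99.96 or above.

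Interferon response genes were modest in level. Of 19 measured members 7 were above 1 RPKM and 7 below, with OAS2 (8.19 ± 1.84) and IRF1 (8.59 ± 4.24) among those above. The list stood at percentile 94.0 of random lists from all genes with a read, and at 0 of those from genes with a mean of at least 1 RPKM. Of 7 MHC genes 2 were above, B2M (29.1 ± 18.7) and CD74 (28.7 ± 7.51), and 5 below, among them SLA-DMB (0.140 ± 0.056), and the main class I genes were not matched by name. Of 10 senescence and arrest genes 8 were above and 1 below, including IGFBP5 (447 ± 184) and the cell cycle inhibitor CDKN1A (209 ± 33.4). Of 19 cell cycle genes 13 were above and 0 below, or 11 adjusted over the list alone. Of 11 hypoxia genes 8 were above and 1 below, including the glycolytic genes LDHA (385 ± 163), ENO1 (223 ± 31.9) and PGK1 (109 ± 30.4). Of 11 immediate early genes 8 were above and 1 below, including DUSP1 (56.9 ± 25.1), IER3 (22.5 ± 6.0) and EGR1 (13.8 ± 3.57). IRF1, B2M and IER3 each overlap another expressed gene, so their values may include its reads. All 10 measured housekeeping genes were above, with RPLP0 at 1740 ± 421 and GAPDH at 903 ± 128 RPKM, and RPL4 at 265 ± 27.5. Of 49 positional homeobox and T-box genes with a read, 15 were above and 25 below (14 and 24 adjusted over the list alone). Those of highest mean CPM were PRRX1 (48.6 ± 7.62), MEIS1 (13.5 ± 3.66) and HOXC6 (5.20 ± 0.998). The 13 mitochondrial genome genes of the list, such as ND1, were listed at 0 in each library. Of the 3 measured sex-linked genes, KDM5D had 0, 4.10 and 4.18 RPKM and EIF1AY 0, 9.38 and 9.34 in cultures 1, 2 and 3, and SRY had 0.090 RPKM in culture 2 and was listed at 0 in the others. XIST and the remaining members of that list were not matched by name.

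**Figure D3:**
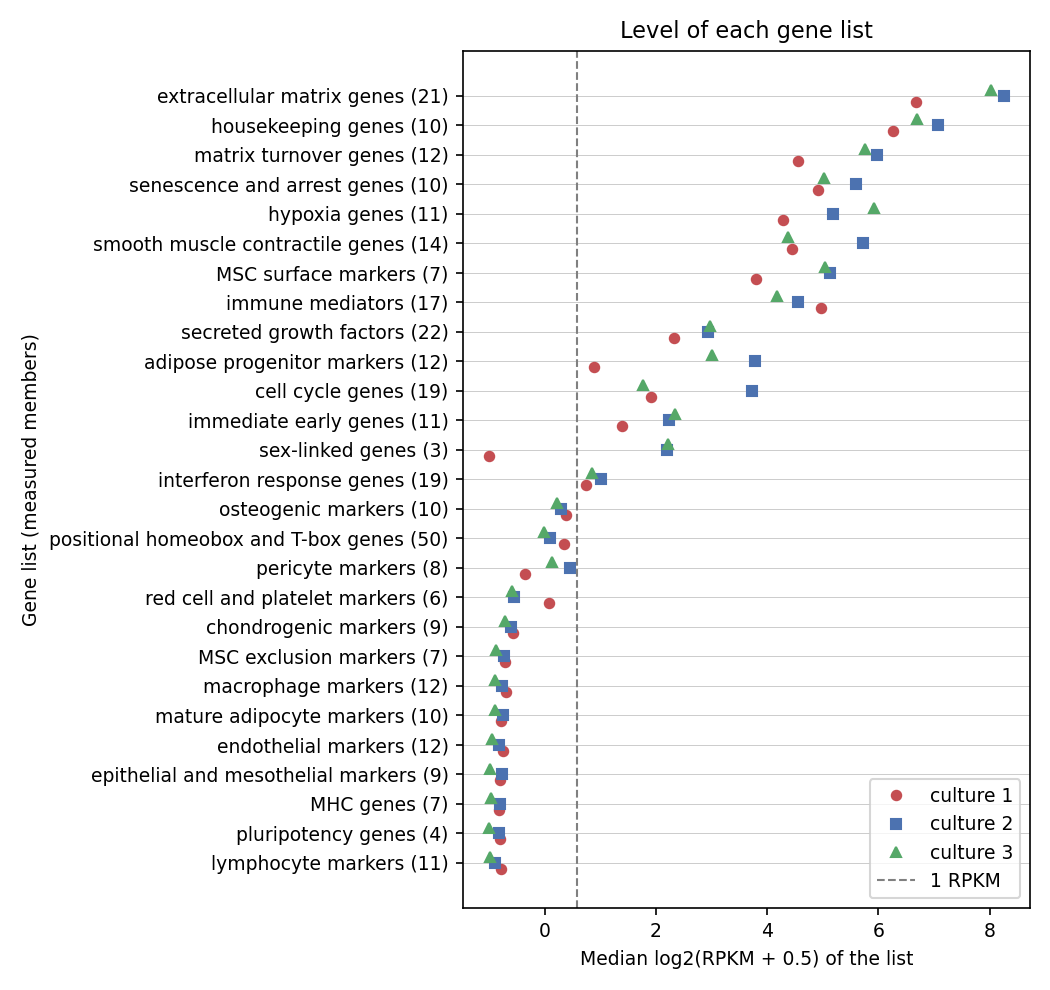
Median log2(RPKM + 0.5) of each gene list (x axis) for the 27 lists with reads (y axis, number of measured members in brackets), with 1 point per culture and 1 RPKM as a dashed line. Extracellular matrix genes lie highest, at a median of 102, 306 and 260 RPKM in cultures 1, 2 and 3.

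Over all genes, 9427 reached 1 RPKM in each of the 3 cultures. In the limma test, 9013 of 29479 genes with a read lay above 1 RPKM and 17925 below. Against a level of 5 RPKM, 4513 genes lay above.

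Among the lists, those of proliferation, contraction, hypoxia and matrix turnover ranged most between the cultures. The cell cycle list had a 3.71-fold range, with culture 2 highest and culture 3 lowest, and stood at percentile 100 of random lists of like level. TOP2A, a topoisomerase of dividing cells, had 15.7, 42.9 and 6.32 RPKM in cultures 1, 2 and 3, CENPF of the kinetochore 2.78, 28.9 and 5.90, and the replication helicase subunit MCM6 8.13, 22.8 and 10.9. Of its 19 members 11 had an unadjusted spread p under 0.05 in limma, and 10 passed when adjusted over the list alone (0 over all genes). Smooth muscle contractile genes ranged 3.11-fold (percentile 99.99), highest in culture 2 and lowest in culture 1. ACTA2 had 107, 817 and 143 RPKM, and without culture 2 the list ranged 1.23-fold and stood at percentile 58.4. Hypoxia genes ranged 3.46-fold (percentile 99.97), from culture 1 as the lowest to culture 3 as the highest, with LDHA at 235, 362 and 558 RPKM and VEGFA, which is on both the hypoxia and the growth factor lists, at 41.3, 115 and 172. Matrix turnover genes ranged 2.61-fold (percentile 99.94), with the same lowest and highest cultures. TIMP3 had 132, 159 and 514 RPKM. The smooth muscle range thus rested largely on culture 2. The other ranges also narrowed with a culture left out, but leaving out the highest or lowest culture can only narrow a range. Cell cycle genes ranged 1.51-fold without culture 2 and still stood at percentile 99.2. Without culture 1 hypoxia genes ranged 1.60-fold (percentile 97.6) and matrix turnover genes 1.29-fold (percentile 91.6). The order of the lists also depended on the scaling, since with median-of-ratios size factors hypoxia genes ranged 4.03-fold and cell cycle genes 2.80-fold. Dividing by these factors (0.996, 1.18 and 0.853 for cultures 1, 2 and 3), in which genes near background weigh, raised culture 3. Yet the median protein-coding gene already lay 0.17 higher on the log2 scale in culture 3 than in culture 1. Ranges with culture 3 as the highest may therefore be overstated under these factors. The library of culture 1, lowest in 3 of these 4 lists, was also the library with 28.2% of small RNA reads.

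Of 18 lists with a value, 11 stood above the 95th percentile of spread, and 10 of these 11 were lowest in culture 1. Besides the 4 above, they were secreted growth factors (1.68-fold, percentile 99.85), MSC surface markers (2.14-fold, percentile 98.1), chondrogenic markers (2.26-fold, percentile 97.7), extracellular matrix genes (1.97-fold, percentile 97.4), adipose progenitor markers (1.90-fold, percentile 97.3), senescence and arrest genes (1.85-fold, percentile 96.6) and osteogenic markers (1.90-fold, percentile 96.0). Only 4 lists stood above the 95th percentile without culture 1, and 3 of them were among the 11, namely the cell cycle, smooth muscle and hypoxia lists. Without culture 1 some ranges almost vanished: growth factors 1.03-fold, MSC surface markers 1.04-fold, extracellular matrix genes 1.05-fold, chondrogenic markers 1.08-fold and senescence genes 1.09-fold. Those of osteogenic and adipose progenitor markers were 1.23-fold and 1.29-fold. With median-of-ratios size factors 13 lists stood above the 95th percentile, among them all 11. Scaled to protein-coding reads, a choice made after seeing the data, 8 lists did, of which 6 were among the 11. MSC surface markers (percentile 77.0), extracellular matrix genes (percentile 28.5), growth factors (percentile 86.8), senescence genes (percentile 59.1) and osteogenic markers (percentile 85.3) then did not. The 2 scalings thus differ on how many lists keep the call. Positional homeobox and T-box genes had the smallest spread for their level (1.11-fold, percentile 3.30), but stood at percentile 97.52 when scaled to protein-coding reads. Housekeeping genes ranged 1.17-fold (percentile 22.6). The other lists with a value were immune mediators (percentile 88.6), interferon response genes (percentile 62.6), macrophage markers (percentile 28.9), lymphocyte markers (percentile 20.03) and immediate early genes (percentile 18.9). Immune mediators passed the 95th percentile without culture 1 (97.8), with median-of-ratios size factors (98.5) and with a pseudocount of 0.1 RPKM (96.1). In the remaining settings they stood at 6.51 to 88.95.

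**Figure D4:**
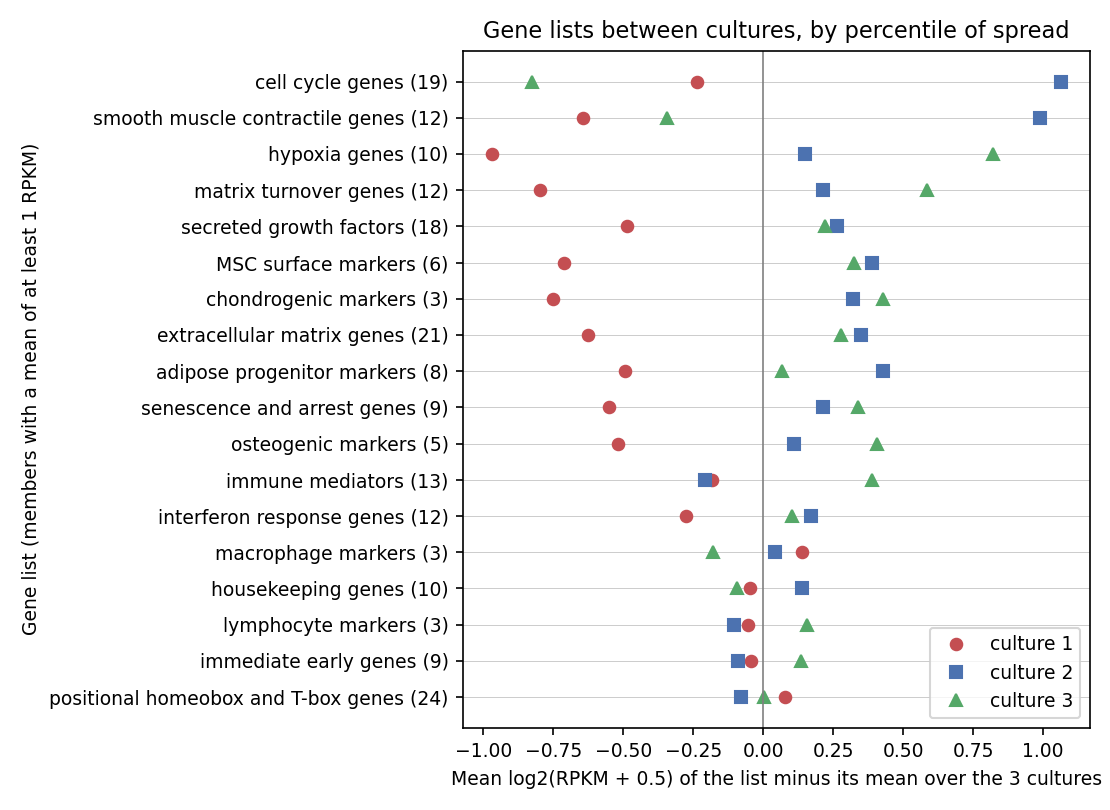
Mean log2(RPKM + 0.5) of each list's members with a mean of at least 1 RPKM, minus the list's mean over the 3 cultures (x axis), for the 18 lists with a value (y axis, ordered by percentile of spread, number of members in brackets), with 1 point per culture. Culture 2 is highest for cell cycle and smooth muscle genes, and culture 1 is lowest in 10 of the 11 lists above the 95th percentile.

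Over all genes, no single gene was called more variable between cultures than the trend. In limma, 0 of 10474 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.36. There were 621 genes with an unadjusted p under 0.05, where the distribution used by the test gives 523.7. That distribution was fitted to these same variances, so a count near it does not show that little varied. The count was 0 with voom weights, 14 with median-of-ratios size factors, 123 of 29479 genes with no filter beyond 1 read and 132 without culture 3. These counts do not compare directly, since the F test also uses limma's prior degrees of freedom. A larger value gives a smaller p for the same large ratio. It was 4.46 in the main fit, 7.28 with the size factors, 30.2 without the filter and infinite without culture 3. The simulation recovered 56% of genes given a log2 SD of 2, and 81% at a log2 SD of 4. Its unchanged genes had spreads more alike than those of these data, so these shares may overstate the recovery here. EIF1AY, with a log2 SD of 2.48 and 52.8 times the trend variance, had an adjusted p of 0.52 in limma. A count of 0 therefore does not show that no gene varied, even by that much. Adjusted over the list alone, both sex-linked genes tested, KDM5D and EIF1AY, passed (smaller adjusted p = 0.0016 in limma). So did 10 of 19 cell cycle, 3 of 12 matrix turnover, 2 of 21 extracellular matrix and 2 of 10 hypoxia genes, and 1 gene in each of the adipose progenitor, osteogenic (SPP1) and pericyte (CSPG4) lists. The median SD of log2(RPKM + 0.5) was 0.31 and the median coefficient of variation of RPKM was 23.9%. The highest culture exceeded the lowest more than 2-fold for 2881 genes (27.5%) and more than 4-fold for 721 (6.88%). The median SD was 0.18 without culture 1, 0.28 without culture 2 and 0.34 without culture 3. These 3 values are over 2 cultures each, so they compare with each other rather than with 0.31. Across genes, Pearson's r of log2(RPKM + 0.5) was 0.920 between cultures 1 and 2, 0.921 between 1 and 3, and 0.958 between 2 and 3, where genes are not independent replicates. The median protein-coding gene lay higher by 0.36 on the log2 scale in culture 2 and by 0.17 in culture 3 than in culture 1.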

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

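The choices made after the data were examined are the scaling to protein-coding reads, voom weights, the pseudocounts of 0.1 and 1 RPKM in the 2 gene tests and for the spread of the lists, a pseudocount of 1 RPKM for the list levels, median-of-ratios factors for the marker difference and the list levels, CPM in place of RPKM for the gene counts and the spread, a filter at a mean of 0.1 RPKM, random lists drawn from genes with a mean of at least 1 RPKM, and protein-coding genes off chromosome Y. The number of genes at 1 RPKM in each culture was 9427 and became 4970 at a level of 5 RPKM, with 9502 to 10104 when a culture was left out. The number above 1 RPKM was 9013 and became 4513 against 5 RPKM, with 8413 to 9313 when a culture was left out. Both counts stayed within 1.5 times under the other scalings, filters, pseudocounts and weights run. The number of genes more variable than the trend was 0 and became 14 with median-of-ratios size factors and 123 with no filter beyond 1 read. With a culture left out it was 0 to 132, the highest without culture 3. There limma's prior degrees of freedom were infinite, against 4.46 with all cultures, which makes the test more lenient. The 132 calls therefore do not by themselves show that more genes varied, and why the prior differed was not tested. The median SD of log2(RPKM + 0.5) was 0.31. It became 0.14 with no filter, which adds genes near 0 whose differences this scale compresses, and 0.18 to 0.34 with a culture left out, the lowest without culture 1. The difference of MSC surface and exclusion markers was 5.43. It became 7.09 with a pseudocount of 0.1 RPKM and 4.57 with 1 RPKM, since the pseudocount sets the level of genes near 0, and lay between 5.19 and 5.89 with a culture left out. The number of lists above the 95th percentile in level was 13 and became 8 against random lists from genes with a mean of at least 1 RPKM, a higher background by construction, with the adipose progenitor (percentile 39.2), growth factor (53.2), cell cycle (29.2), immediate early (9.54) and positional homeobox (0) lists losing the call, and 12 to 13 when a culture was left out. The number of lists above the 95th percentile in spread was 11 and 4 to 10 with a culture left out, the lowest without culture 1. It was 13 with median-of-ratios size factors and 8 when scaled to protein-coding reads. Without culture 1 the range of the hypoxia list fell from 3.46-fold to 1.60-fold and that of matrix turnover genes from 2.61-fold to 1.29-fold. Without culture 2 the range of the cell cycle list fell from 3.71-fold to 1.51-fold and that of smooth muscle genes from 3.11-fold to 1.23-fold. The cell cycle and hypoxia lists stayed above it in each of the 10 settings (lowest percentiles 99.2 and 97.6). Among 3077 values of list members and other tabulated genes against 1 RPKM under the alternatives, 2874 kept their side of the threshold, 75 lost a call, 128 gained one, and 0 turned direction. Not run were the planned count-model tests and scalings (the Wald and dispersion-outlier tests, the goodness-of-fit test and trimmed-mean scaling). They were left out by choice because the deposited unit is RPKM, although whole reads could be recovered. Leaving out mitochondrial genes removes no tested gene. No paired analysis was possible because the labels give a single group. Depth limits levels under about 0.03 RPKM in a 2 kb gene, where a library holds fewer than 3 reads.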

Other observations

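The explanations of reads counted over overlapping entries and of reads crossing between libraries were tested after the values they measure had been seen. The other tests were set out before.

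Sex-linked transcripts divided the cultures. Of 14 genes on chromosome Y with at least 2 RPKM in both cultures 2 and 3, 10 had under 1% of that level in culture 1, among them KDM5D, a histone demethylase, and EIF1AY, a translation factor. The other 4 genes on that chromosome were read in culture 1 as well, at up to 106% of the level in the others. Among them, ENSSSCG00000039894, ENSSSCG00000039926 and ENSSSCG00000048323 lie between 5946970 and 7687943, before the 10, which start at 8987555 or later. ENSSSCG00000039365 lies among the 10. Whether reads of these 4 genes came from chromosome X was not tested. In the opposite direction, a pair of unnamed lncRNA genes on chromosome X, singled out after their values were seen, were read almost only in culture 1. They are ENSSSCG00000044599 (59283918 to 59286152), with 33.4, 0.039 and 0 RPKM in cultures 1, 2 and 3, and ENSSSCG00000049776 (59288879 to 59293232), with 43.5, 0 and 0.025 RPKM.

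A candidate explanation is that the donor animals differed in sex, which the labels do not give. It was tested on the reads over silent genes, defined as genes with at most 0.02 RPKM in culture 3. Their density on chromosome X relative to the autosomes was 2.02 times higher in culture 1 than in culture 2, as that explanation needs. Whether a sample was mixed up was not tested.

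Reads over genes that should be silent differed between libraries: of 105 olfactory receptor genes, 89.5%, 91.4% and 40% had a read in cultures 1, 2 and 3. Genomic DNA in the libraries of cultures 1 and 2 may be the source. It predicts a density on chromosome X that follows the number of X chromosomes, and the X to autosome ratio over silent genes was 0.56 in culture 2 (95% bootstrap interval 0.52 to 0.62, 439 X-linked and 7789 autosomal genes), which has Y-linked transcripts, and 1.13 in culture 1 (1.09 to 1.21), where single autosomes ranged from 0.81 to 1.06. The median over silent autosomal genes was 0.049 RPKM in culture 1, 0.038 in culture 2 and at most 0.02 in culture 3 by definition. Reads crossing from cultures 2 and 3 could therefore not by themselves supply the density in culture 1. That density was 1586 times what the level of Y-linked genes there allows. With sources this low, that test could not have come out otherwise, so nothing is concluded from it. Crossing from libraries outside this series was not tested. The X to autosome ratios bear on both donor sex and genomic DNA, so the tests of those are not independent. No biological explanation of the background was tested.

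Small non-coding RNA took 28.2% of the reads in culture 1 against 9.08% and 8.33% in the others, and 234 of 272 small RNA loci with a mean of at least 10 RPKM (86.0%) were highest in culture 1. With 1 entry kept per locus the shares were 20.6%, 5.79% and 5.45%, that of culture 1 still 3.66 times the mean of the others. The difference thus remained without double counting over overlapping entries. The overlaps are the same in all 3 libraries, and 1689 entries became 1683 loci. This test could therefore hardly have come out otherwise, and nothing further is concluded from it. Less effective poly(A) selection may have contributed. Replication-dependent histone genes, whose mRNAs mostly but not always lack a poly(A) tail, were higher in culture 1 by a median of 0.87 on the log2 scale (95% bootstrap interval 0.43 to 1.38, 10 genes). This lay between the bounds of 1 and 0.5 set for and against less effective selection. Set against the median over all protein-coding genes, which was -0.26, the same difference was 1.12, past the bound of 1, but the bounds were set for the plain difference. Each of the 10 genes was lowest in culture 3, and H1-4, H1-3, HIST1H3E and H2BC11 were lower in culture 1 than in culture 2. Culture 3 was also lowest on the cell cycle list, and a link of the histone difference to replication was not tested. Less effective poly(A) selection thus stays open. A preference for short transcripts likewise stays open, since the median difference of culture 1 from the others in the longest protein-coding genes minus that in the shortest (the top and bottom of 5 equal bins of length) was -0.43 on the log2 scale (-0.47 to -0.40), between the bounds of 0.5 and 0.2 in size. With 1 library of this kind these explanations cannot be told apart, and no biological explanation was tested.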
